A study of Mus musculus with 85 samples.

How the data were processed

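Expression was measured on 85 single-colour Mouse Gene 1.0 ST arrays of sorted Tconv and Treg in 30 groups, each group being a cell type, an antibody and a time pool per the labels. The submitters' processing notes name Affymetrix Power Tools and the RMA algorithm for background correction and normalization. The deposited values are probe set intensities on the linear scale, 1 per probe set and array, and log2 was taken here, since RMA itself gives log2 values. The scale was read from the values, which are all positive with similar medians. Raw scanner files were not used here. Median intensity per array lay between 112.2 and 132.2 units and the upper quartile between 290 and 399 units. Arrays carry no count of molecules, so the number of arrays and the signal over background set the precision.

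The 24922 probe sets were named through the platform annotation table: 21425 had 1 gene symbol, 1399 several and 2098 none. Only probe sets with 1 symbol were used, and 21347 of them matched a current gene by Entrez ID, with 0 symbols changed. Genes whose probe sets carry several symbols or none were not analysed here. For the 921 genes with several probe sets the one with the highest mean was kept. In 643 of these a further probe set passed the floor, and in 123 of the 643 the kept one and the next correlated with r below 0.5 across arrays. Of 19752 genes, 11706 reached 7 on the log2 scale (128 units) in at least 2 arrays and were tested, and 8046 did not.

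Group means were fitted over all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), with 55 residual degrees of freedom. Within each comparison p values were adjusted by the Benjamini-Hochberg method and a gene was called under 0.05. Comparisons were anti-CD3 only against unstimulated cells, resting Treg against resting Tconv, each of 6 antibodies against anti-CD3 only per cell type and pool, anti-ICOS against anti-CD28, and the difference of effects between Treg and Tconv. The late response to anti-CD3 was not compared between cell types, because the late pools differ in time.

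The design, the 21 gene lists, the rule for naming genes and the main alternatives were set before the data were examined. The lists were immediate early genes, T cell cytokines, IL-2 and STAT5 targets, NF-kappaB targets, S phase, G2 and M phase, ribosome biogenesis, glycolysis, cholesterol synthesis, amino acid transport and ATF4, quiescence and naive state, Treg signature, T helper and follicular helper genes, costimulatory receptors and ligands, anergy linked genes, interferon stimulated genes, heat shock and stress, and markers of B cells, of myeloid and dendritic cells, of CD8 and NK cells and of erythroid cells and platelets. They were tested with camera (preset correlation 0.01, then an estimated one) and fry, adjusted over the lists of a comparison, and called members were counted over all genes and adjusted over the list alone. Up to 10 called genes with the largest rise and up to 10 with the largest fall, whose groups of arrays did not overlap, could be named in order of size; overlap was not asked of differences of effects. Of each list the called members could be named in order of absolute change, at most 4, or the largest where none was called. Foxp3 and the costimulatory list were always reportable.

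The activation score of an array is the mean of genes induced at least 2-fold by anti-CD3 minus the mean of those repressed, taken from the other cell type at the same pool, tested by an exact permutation of arrays and by fry. Correlations with the anti-CD28 effect were computed with shared controls, with controls split 2 and 2, and for simulated unchanged groups.

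Replicate numbers in the labels were checked for pairing. Deviations from the group mean correlated on average with r = 0.327 between arrays with the same number and with -0.127 between others. Of 16 comparisons with 3 or more shared numbers, 12 had every pair above r = 0.1 and were taken as paired: anti-CD28 in Tconv at both times and in early Treg, anti-CTLA-4 in all 4 settings, anti-PD-1 in Tconv at both times, and anti-BTLA in Tconv at both times and in early Treg. The labels do not say what a number marks, so this pairing comes from the data. In the fit with a replicate block the number was a fixed term over all arrays.

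Alternatives were no floor, cyclic loess between arrays, 32 units added before log2, a fit with only the groups compared, the replicate block, Treg and Tconv arrays of the same antibody, pool and number as a random block (estimated correlation 0.244), activation genes of the same cell type, and each array left out in turn. Where this leaves 1 array in a group, that array is assumed to vary like the other groups. Leaving out the early Treg arrays numbered 1, the upper quartile as a covariate, and the replicate block for lists and correlations were added after seeing the data.

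The pipeline was tested on 11706 simulated genes with known changes, which need not vary like real arrays. With the group sizes of anti-CD28 in late Tconv it recovered 45.6%, 92.4% and 100.0% of log2 changes of 0.5, 1 and 2. False calls were 5.95%. With 2 arrays against 4 (anti-ICOS) it recovered 39.7%, 90.9% and 100.0%, and for differences of effects 16.2%, 74.2% and 97.0%. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.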

Results

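Expression was measured on 85 Mouse Gene 1.0 ST arrays, 43 from conventional CD4 T cells (Tconv) and 42 from regulatory T cells (Treg) of male C57BL/6J mice aged 8 weeks. CD4 T cells from spleen and lymph node had been stimulated with an antibody to CD3, the signalling part of the T cell receptor complex, alone or together with an antibody to CD28, ICOS, CTLA-4, PD-1, BTLA or CD80. CD28 and ICOS are costimulatory receptors, CTLA-4, PD-1 and BTLA are receptors known to restrain T cells, and CD80 is a ligand of CD28 and CTLA-4. Both cell types were sorted from the same stimulated cultures by the GFP reporter of Foxp3, the transcription factor that defines Treg. Lysates of 1 and 4 h were pooled into an early sample. Lysates of 20 and 48 h were pooled into a late sample for Tconv, whereas the late sample of Treg holds 20 h only, so the late samples of the cell types differ in time as well as in cell type. The 30 groups are unstimulated cells (3 arrays per cell type), anti-CD3 only (4 arrays per cell type and pool), anti-CD28, anti-CTLA-4, anti-PD-1 and anti-BTLA (3 arrays each, but 2 for anti-PD-1 in early Treg), and anti-ICOS and anti-CD80 (2 arrays each). That the label CD3 without a second antibody means anti-CD3 only was inferred from the other labels. The median probe set intensity lay between 112 and 132 units on every array, and the number of arrays limits the precision, for dim genes also the signal over background. Log2 changes below are given ± the standard error (SE) of limma's model over all arrays.

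Cell type and time of stimulation were the main axes of variation. Foxp3 was at 12.04 or higher on the log2 scale in each of the 42 Treg arrays and at 8.01 or lower in each of the 43 Tconv arrays. The first principal component, with 32.4% of the variance, ran from Tconv to Treg, and the second, with 17%, from unstimulated Tconv and early samples to late samples. Replicates of a group correlated with a median r of 0.975 across genes. The lowest r between a pair of replicates was 0.925.

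**Figure D1:**
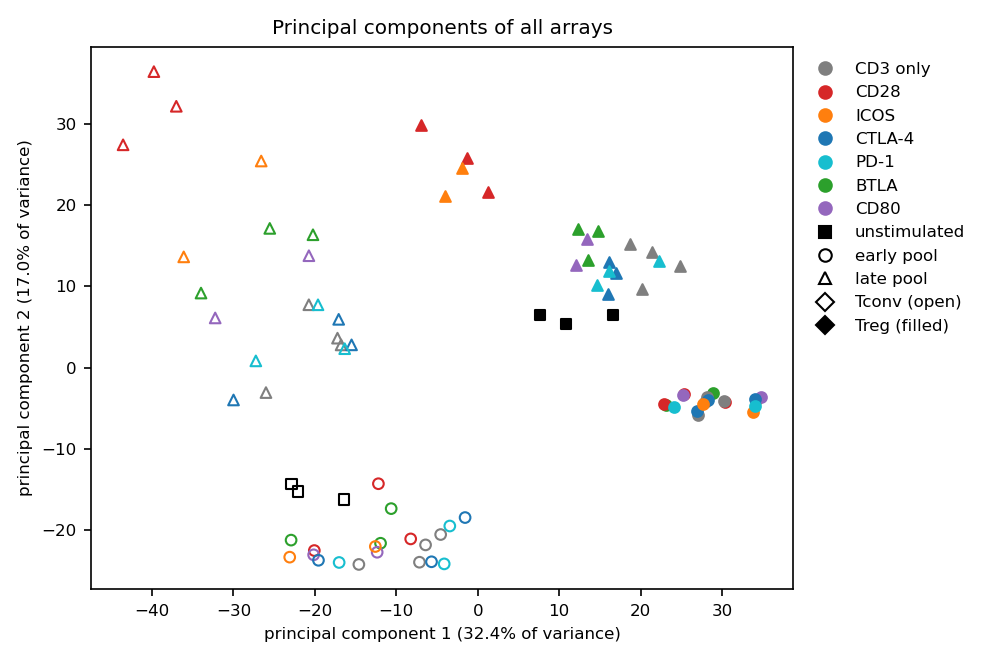
Scores of the 85 arrays on principal components 1 and 2 (horizontal and vertical axis, log2 scale units), with 32.4% and 17% of the variance. Colour gives the antibody, shape the time pool and filling the cell type. Tconv lie at negative values of component 1 and most Treg at positive values, and late arrays lie above early arrays of the same cell type.

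The comparison of unstimulated Treg with unstimulated Tconv asks how the cell types differ before stimulation. Treg had more of the transcripts that serve their suppressive programme: Lrrc32, which presents latent TGF-beta, was higher by 4.93 ± 0.18, Foxp3 by 4.52 ± 0.11, the IL-2 receptor chain Il2ra by 4.50 ± 0.21 and Socs2 by 3.75 ± 0.26. All 27 measured members of the Treg signature passed the test upward, 27 of them also adjusted over the list alone, with a median log2 difference of 2.64 and all 3 Treg arrays above the Tconv arrays. Transcripts lower in Treg were led by the phosphodiesterase Pde3b at -4.23 ± 0.30 and the VIP receptor Vipr1 at -3.18 ± 0.21.

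Receptors and ligands of costimulation were already higher in resting Treg. Of 20 measured members 13 passed the test upward (15 adjusted over the list alone), led by Ctla4 at 3.00 ± 0.18, Tnfrsf4 (OX40) at 2.83 ± 0.16 and Tigit at 2.62 ± 0.17. The IL-2 and STAT5 targets had 11 of 19 members higher and 3 lower (11 and 3 adjusted over the list alone), and the NF-kappaB targets 8 of 18 higher (11 adjusted over the list alone), with Cd83 at 2.64 ± 0.13 and Rel at 1.07 ± 0.22. Among T helper genes 8 of 17 were higher (8 adjusted over the list alone) and 1 lower, with Ccr6 first at 1.97 ± 0.17. Of 22 quiescence genes 9 were lower, led by Dapl1 at -2.35 ± 0.27 and Igfbp4 at -2.10 ± 0.21 (camera adjusted p = 2.41e-06; adjusted p = 0.078 with an estimated correlation). The G2 and M phase list had 13 of 24 members higher, Mki67 first at 1.45 ± 0.46, with an adjusted p of 9.31e-10 that became 0.0975 with an estimated correlation. Ribosome biogenesis had 9 of 24 members lower (adjusted p = 0.000151; adjusted p = 0.214 with an estimated correlation), Wdr12 first at -1.08 ± 0.19. These last 3 counts were 9, 16 and 11 adjusted over the list alone. The call of Mki67 ended without Tconv replicate 3 or 4 or Treg replicate 4 or 5 (adjusted p up to 0.101).

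Markers of other cell types were tested beside these lists. Of 13 B cell markers measured 9 lay under the floor. Among the 4 tested Cd74, the invariant chain of MHC class II, was higher in Treg by 1.84 ± 0.22, Cd79b of the B cell receptor by 1.71 ± 0.13 and Fcmr by 1.29 ± 0.15 (3 adjusted over the list alone). The list mean was 7.95 ± 0.23 (SD, 3 arrays) in resting Treg and 6.73 ± 0.18 in resting Tconv, although the sort gated out B220. Treg replicate 3 had the highest mean of the B cell markers, 8.21, and of the myeloid and dendritic markers, 8.75. No myeloid or dendritic marker passed the test (0 of 4 tested, limma, with 12 under the floor; Ctss largest at 0.38 ± 0.19), and none of the 4 tested erythroid and platelet markers did (Ppbp largest at 0.64 ± 0.43). Of 5 tested CD8 and NK markers Klrd1 alone passed, at -2.39 ± 0.27 (3 lower adjusted over the list alone). In all, limma called 698 genes higher and 1136 lower in resting Treg out of 11706 tested. Cyclic loess between arrays shifted the log2 difference of all genes by a median of 0.11 and gave 857 higher and 687 lower, and relative to that shift the Treg signature median was 2.76 and the ribosome biogenesis median -0.25. Without Treg replicate 5 the total of 1834 fell to 1157.

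Anti-CD3 only was compared with unstimulated cells of 0 h, so anti-CD3 cannot be told apart from time in culture. In early Tconv the nuclear receptors of the Nr4a family, immediate targets of T cell receptor signalling, rose most: Nr4a2 by 4.24 ± 0.28, Nr4a3 by 3.67 ± 0.25 and Nr4a1 by 2.96 ± 0.17, together with the transcription factor Irf4 by 2.97 ± 0.14. In early Treg Nr4a2 rose by 3.82 ± 0.28, Ramp3 by 3.70 ± 0.22, Vps37b by 3.09 ± 0.18 and the AP-1 member Fosl2 by 3.01 ± 0.17. The immediate early list of 25 genes had 13 members up and 2 down in Tconv and 14 up and 0 down in Treg (14 and 4, and 16 and 0, adjusted over the list alone; camera adjusted p = 7.94e-14 and 3.36e-16), with all 4 arrays above the unstimulated ones in each cell type. Of 18 NF-kappaB targets 9 rose in Tconv and 13 in Treg (10 and 13 adjusted over the list alone), and Tnfaip3, a feedback inhibitor of NF-kappaB, came first in both at 1.97 ± 0.18 and 2.23 ± 0.18.

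Early stimulation also moved the transcripts of costimulatory molecules. In Tconv 9 of 20 rose and 2 fell, with Tnfrsf9 (4-1BB) at 1.90 ± 0.16, Tigit at 1.64 ± 0.16 and Cd274 (PD-L1) at 1.53 ± 0.19. In Treg 10 rose and 3 fell, with Pdcd1 (PD-1) at 1.60 ± 0.16, Cd80 at 1.17 ± 0.25, Tnfrsf9 at 1.16 ± 0.16 and Ctla4 at 1.11 ± 0.17 (list adjusted p = 0.000126; adjusted p = 0.0929 with an estimated correlation). Of 20 T cell cytokines 5 rose in Tconv and 1 fell, Tnfsf11 first at 1.08 ± 0.16 and Fasl next at 1.07 ± 0.20; the list's adjusted p of 0.0397 became 0.204 with an estimated correlation and 0.0821 after cyclic loess. Of 13 anergy linked genes 4 rose and 1 fell, led by Egr2 at 2.17 ± 0.23 and Egr3 at 1.58 ± 0.30, with adjusted p = 0.0442, 0.204 with an estimated correlation and 0.0674 after cyclic loess. Interferon stimulated genes fell: 11 of 16 in Tconv and 11 of 16 in Treg, led in both by Ifit3 at -1.65 ± 0.40 and -1.52 ± 0.40 and Usp18 at -1.56 ± 0.31 and -1.15 ± 0.31 (adjusted p = 9.99e-05 and 0.000208; adjusted p = 0.204 and 0.24 with an estimated correlation). Adjusted over the list alone the costimulatory counts were 9 up and 3 down in Tconv and 10 and 4 in Treg, the cytokines 5 and 1, the anergy genes 4 and 3, and the interferon genes down 11 and 12. Altogether limma called 808 genes up and 1199 down in early Tconv and 922 up and 1160 down in early Treg. Without unstimulated Tconv replicate 3 the early Tconv total of 2007 fell to 1153.

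In late Tconv the largest rises were those of the steroid-metabolizing enzyme Akr1c18 at 3.67 ± 0.23, Pros1 (protein S) at 3.38 ± 0.33 and Il2ra at 3.37 ± 0.20. The largest falls were those of Slc16a5 at -3.18 ± 0.21, Igfbp4 at -3.05 ± 0.19 and Dtx1 at -3.04 ± 0.16. Genes of DNA replication rose together, 16 of 28 in the S phase list, led by Dtl at 1.49 ± 0.20, Uhrf1 at 0.92 ± 0.16 and the helicase subunit Mcm6 at 0.89 ± 0.12 (adjusted p = 7.52e-10; 0.0428 with an estimated correlation). Ribosome biogenesis rose in 13 of 24 members, 17 adjusted over the list alone, with nucleolin (Ncl) at 1.28 ± 0.20 and dyskerin (Dkc1) at 1.03 ± 0.31 (adjusted p = 1.18e-09; adjusted p = 0.0667 with an estimated correlation). Of the costimulatory list 9 rose and 2 fell, with Tnfrsf9 at 2.87 ± 0.16, Cd274 at 1.66 ± 0.19 and Tnfrsf4 at 1.52 ± 0.15. Of 22 quiescence genes 8 fell and 2 rose, Igfbp4 and Rasgrp2 (-1.56 ± 0.18) first (adjusted p = 0.00448; adjusted p = 0.301 with an estimated correlation). Of S phase and costimulatory genes 16 and 11 were up adjusted over the list alone, and 3 costimulatory and 9 quiescence genes down. The test by limma called 722 genes up and 1284 down, and without unstimulated Tconv replicate 3 the total of 2006 fell to 1215. The call of Dkc1 ended without anti-CD3 replicate 4 or unstimulated replicate 3 or 4 (adjusted p up to 0.151).

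Late Treg given anti-CD3 only, sampled at 20 h, raised the chemokine Ccl3 by 2.54 ± 0.46, the GTPase Iigp1 by 2.38 ± 0.29 and the phosphatase Phlpp1 by 2.25 ± 0.22. Dtx1 fell by 2.89, Igfbp4 by 2.59 and Fos by 2.38. IL-2 and STAT5 targets rose in 8 of 19 members and fell in 2, with granzyme B (Gzmb) at 1.56 ± 0.33 and Socs2 at 1.17 ± 0.24 (adjusted p = 3.32e-05; 0.0436 with an estimated correlation). Proliferation genes fell, 7 of 28 in the S phase list with Rrm2 at -1.11 ± 0.21, and 12 of 24 in the G2 and M phase list with Ccna2 at -1.38 ± 0.29. The adjusted p of 5.87e-07 and 2.35e-09 became adjusted p = 0.078 and 0.106 with an estimated correlation. Heat shock genes fell in 8 of 11 members, led by Hsph1 at -1.50 ± 0.16 and Dnajb1 at -1.43 ± 0.19 (adjusted p = 4.01e-09; 0.013 with an estimated correlation). Of the costimulatory list 8 rose and 1 fell, Cd274 first at 1.32 ± 0.19 (adjusted p = 0.000728; adjusted p = 0.102 with an estimated correlation). The B cell markers fell as well, Cd74 by 0.95, Cd79b by 0.73 and Fcmr by 0.42, from a list mean of 7.95 to 7.44. Adjusted over the list alone 11 IL-2 and STAT5 targets and 9 costimulatory genes were up, and 10 S phase, 16 G2 and M phase, 9 heat shock and 3 B cell marker genes down. Over all genes limma called 497 genes up and 623 down, and without unstimulated Treg replicate 3 the total of 1120 fell to 657. That of Fcmr ended without anti-CD3 replicate 1 or 3 or unstimulated replicate 3 (adjusted p up to 0.559, at -0.21 without the last).

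Anti-CD28 was then compared with anti-CD3 only, which asks what classical costimulation adds. In early Tconv the growth factor Il2 rose most, by 2.50 ± 0.37, and the transcription factors Irf8 at 1.88 ± 0.24, Tbx21 (T-bet) at 1.51 ± 0.25 and Myc at 1.40 ± 0.26 rose as well, as did Cxcl10 at 1.25 ± 0.24. Of 20 T cell cytokines 5 rose (13 adjusted over the list alone), with Tnf at 1.00 ± 0.21 and Lif at 0.93 ± 0.15 after Il2, and the list shifted by a median of 0.50 (camera adjusted p = 4.68e-22; 3 of 3 arrays above all anti-CD3 arrays). The ribosome biogenesis list shifted by a median of 0.41, with 5 of 24 called (15 adjusted over the list alone), led by Polr1b of RNA polymerase I at 0.78 ± 0.16 and Noc4l at 0.67 ± 0.13. Smaller parts of other lists rose: 4 of 25 immediate early genes with Spry1 at 0.97 ± 0.21, 4 of 19 IL-2 and STAT5 targets with Il2ra at 1.29 ± 0.20 and Cish at 1.16 ± 0.17. Likewise 4 of 17 genes of amino acid transport and ATF4 rose with Slc7a5 at 0.57 ± 0.12 and 3 of 18 NF-kappaB targets with Nfkbid at 0.74 ± 0.15 (the 4 lists had 7, 7, 6 and 5 adjusted over the list alone). The 2 genes lower were Heatr5a at -0.67 ± 0.13 and Rcan3 at -0.52 ± 0.12. In all, limma called 82 genes up and 2 down, 172 in total with replicate number as a block and 2 with only the groups compared. The total of 84 fell to 28 without anti-CD28 replicate 3, and to 55 without anti-CD3 replicate 2 or replicate 4. Without anti-CD28 replicate 3 the calls of Nfkbid, Noc4l, Polr1b, Rcan3, Slc7a5, Spry1 and Tnf ended (adjusted p from 0.0575 to 0.807, with Polr1b at 0.47), Spry1 also without anti-CD28 replicate 1 (0.053) and Rcan3 without anti-CD3 replicate 1 (0.0614).

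In early Treg anti-CD28 raised a set of 20 genes and lowered 0, with limma; Tbx21 rose by 1.44 ± 0.25, the Treg receptor Gpr83 by 1.12 ± 0.18, Irf8 by 1.11 ± 0.24 and Sema7a by 1.11 ± 0.15. Of the IL-2 and STAT5 targets 2 of 19 rose, the feedback inhibitor Socs1 at 0.81 ± 0.17 and the survival gene Bcl2l1 at 0.67 ± 0.15 (5 adjusted over the list alone; list adjusted p = 2.78e-12). Of 20 cytokines 2 rose, Lta at 0.90 ± 0.18 and Lif at 0.82 ± 0.15 (4 adjusted over the list alone). Ribosome biogenesis had 0 of 24 members called by limma and 3 adjusted over the list alone, while the list shifted by a median of 0.25 (adjusted p = 3.58e-13; 3 of 3 arrays above all anti-CD3 arrays). An unadjusted p under 0.05 was reached by 558 genes, or 4.767% of those tested, near the share of 0.05 that chance gives. With replicate number as a block 66 genes were called. The count of 20 fell to 7 and 4 without anti-CD28 replicates 2 and 3, and to 9, 12 and 13 without anti-CD3 replicates 2, 3 and 4. The calls of Bcl2l1, Irf8 and Socs1 ended without any of several arrays, anti-CD28 replicates 2 and 3 among them (adjusted p up to 0.671, 0.216 and 0.227), that of Lta without anti-CD28 replicate 2 or 3, and those of Lif and Tbx21 without replicate 3 (0.137 and 0.0595).

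In late Tconv anti-CD28 was followed by a broad proliferative and metabolic programme. All 28 measured S phase genes rose, by a median of 1.73, led by ribonucleotide reductase Rrm2 at 2.87 ± 0.21, cyclin Ccne2 at 2.69 ± 0.24 and Dtl at 2.59 ± 0.20. All 24 G2 and M phase genes rose, by a median of 2.62, led by the spindle checkpoint kinase Bub1 at 3.67 ± 0.33, Hmmr at 3.23 ± 0.21 and cyclin Ccna2 at 3.14 ± 0.29. Glycolysis rose in 13 of 14 members with Tpi1 at 2.22 ± 0.16 and the lactate exporter Slc16a3 at 1.88 ± 0.17, and cholesterol synthesis in 17 of 17 with Lss at 1.36 ± 0.16 and Fdps at 1.36 ± 0.16. The same counts held adjusted over each list alone, and every list had an adjusted p of 4.11e-12 or lower and 3 of 3 arrays above all anti-CD3 arrays.

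Further groups in late Tconv were amino acid genes, cytokine signalling and quiescence. Asns rose by 2.58 ± 0.25 and Psat1 by 1.55 ± 0.13 among 10 of 17 members of the amino acid list. Of 19 IL-2 and STAT5 targets 13 rose and 1 fell, with Socs2 at 3.16 ± 0.24 and Il2rb at 1.75 ± 0.13. Of 22 genes of the naive and quiescent state 16 fell and 1 rose, led by the IL-7 receptor Il7r at -2.19 ± 0.22, the egress receptor S1pr1 at -1.95 ± 0.23 and Pik3ip1 at -1.69 ± 0.18 (adjusted p = 2.46e-12). The costimulatory list moved both ways, 7 up and 7 down, with Lag3 at 1.51 ± 0.17, Ctla4 at 1.45 ± 0.17 and Tigit at 1.31 ± 0.16. When adjusted over the list alone 10 amino acid genes and 15 IL-2 and STAT5 targets were up, 17 quiescence genes down, and 8 costimulatory genes up and 8 down. Among single genes the desaturase Scd2 rose by 3.53 ± 0.23, the oxygen sensor Egln3 by 3.35 ± 0.28 and Il12rb2 by 3.34 ± 0.30. Altogether limma called 2243 genes up and 1196 down.

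In late Treg anti-CD28 raised replication and ribosome genes without a comparable shift of mitotic genes. All 28 S phase genes rose, by a median of 0.93, led by Dtl at 2.11 ± 0.20 and Rfc4 at 1.61 ± 0.26. All 24 ribosome biogenesis genes rose, by a median of 1.07, led by Nop58 at 1.72 ± 0.25 and Gnl3 at 1.47 ± 0.17. Of the G2 and M phase genes 4 of 24 rose (3 adjusted over the list alone), Bub1 at 1.11 ± 0.33 and Top2a at 1.07 ± 0.28 first, and the list median was 0.09 (adjusted p = 0.253; 0.0413 after cyclic loess and 0.0144 without the filter on dim genes). Of 17 amino acid genes 11 rose with Psat1 at 1.67 ± 0.13, and 10 of 18 NF-kappaB targets rose with Bcl2l1 at 1.33 ± 0.15 (NF-kappaB list adjusted p = 0.000221; adjusted p = 0.0636 with an estimated correlation). Glycolysis rose in 9 of 14 with Tpi1 at 1.27 ± 0.16 (adjusted p = 0.103 with an estimated correlation), and 13 of 22 quiescence genes fell with Il7r at -1.37 ± 0.22 and S1pr1 at -1.25 ± 0.23 (adjusted p = 0.0636 with an estimated correlation). The counts adjusted over the list alone were 28 for S phase, 24 for ribosome biogenesis, 11 for amino acids, 11 for NF-kappaB, 10 for glycolysis and 13 for quiescence. Of single genes Tbx21 rose most, by 2.16 ± 0.25, and Tmem71 fell most, by 1.95. The test by limma called 2048 genes up and 941 down, or 1813 up and 1425 down after cyclic loess. Without anti-CD28 replicate 3 the total of 2989 fell to 1748. The call of Bub1 ended without anti-CD28 replicate 1 (adjusted p = 0.0739).

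**Figure D2:**
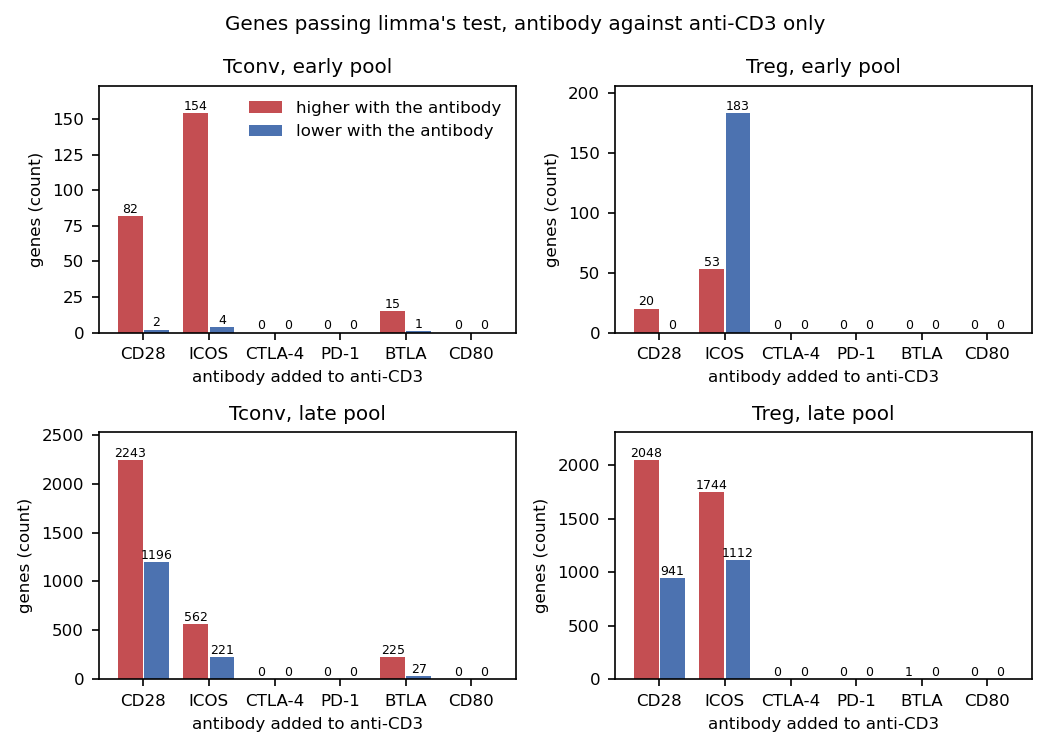
Number of genes (vertical axes, each from 0 on its own scale) that passed limma's test higher or lower with each antibody than with anti-CD3 only, per cell type and time pool, of 11706 tested. Bars for CD28 and ICOS stand in all 4 panels, BTLA has 225 and 27 in late Tconv, and CTLA-4, PD-1 and CD80 stand at 0 throughout.

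Anti-ICOS was compared in the same way, with 2 arrays per group. In early Tconv Tbx21 rose by 2.46 ± 0.28, Irf8 by 2.17 ± 0.27, Sema7a by 2.00 ± 0.17, Ccl3 by 1.97 ± 0.53 and Il2 by 1.85 ± 0.42. Of 20 cytokines 9 rose (14 adjusted over the list alone), with Lif at 1.83 ± 0.17 and Tnf at 1.42 ± 0.24 (camera adjusted p = 5.24e-21; 2 of 2 arrays above all anti-CD3 arrays). Of 16 interferon stimulated genes 3 rose (12 adjusted over the list alone), Oasl2 at 1.15 ± 0.27, Irgm1 at 1.01 ± 0.15 and Isg20 at 0.71 ± 0.19. Ribosome biogenesis rose in 8 of 24 with Rrs1 at 1.47 ± 0.34 (12 adjusted over the list alone), and 4 of 25 immediate early genes rose with Myc at 1.63 ± 0.30 and Atf3 at 1.51 ± 0.22 (19 adjusted over the list alone). Over all genes limma called 154 genes up and 4 down. The total of 158 fell to 46 and 56 without anti-ICOS replicates 1 and 2, and to 104 without anti-CD3 replicate 3. The calls of Ccl3, Isg20, Oasl2 and Rrs1 ended without either anti-ICOS array (adjusted p up to 0.417, 0.427, 0.286 and 0.239), the first 3 also without anti-CD3 replicate 4, and those of Il2 and Myc without anti-ICOS replicate 1 (0.342 and 0.062). With only the groups compared 65 genes were called.

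In late Tconv anti-ICOS raised Ccr8 by 3.33 ± 0.31, Nkg7 by 3.03 ± 0.30, Il12rb2 by 2.85 ± 0.34, H2ac4 by 2.85 ± 0.56 and Il3 by 2.54 ± 0.49. The S phase list rose in 27 of 28 members by a median of 1.11, with Rrm2 at 1.82 ± 0.24. The G2 and M phase list rose in 20 of 24 by a median of 1.54, with Ccnb2 at 2.35 ± 0.23 and Ccna2 at 2.29 ± 0.33 (28 and 22 adjusted over the list alone; adjusted p = 7.9e-50 and 6.09e-51). IL-2 and STAT5 targets rose in 8 of 19 with Gzmb at 1.76 ± 0.37. T helper genes rose in 5 of 17, with Tbx21 at 2.37 ± 0.28, Eomes at 1.76 ± 0.23 and Gata3 at 1.08 ± 0.16 after Il12rb2 (adjusted p = 0.00201; adjusted p = 0.0586 with an estimated correlation). Of 22 quiescence genes 9 fell, Il7r first at -1.79 ± 0.25. These 3 counts were 10, 5 and 12 adjusted over the list alone. In all, limma called 562 genes up and 221 down, or 373 in total with only the groups compared, and without anti-ICOS replicate 1 the total of 783 fell to 266. That of Gzmb ended without anti-ICOS replicate 1 (adjusted p = 0.0797).

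Early Treg given anti-ICOS had more genes lower than higher with all arrays. Klrg1, a receptor of short-lived effector Treg, fell by 2.00, cyclin Ccna2 by 1.86, the chemokine receptor Ccr2 by 1.65 and Atp6v0d2 by 1.48. In turn Tbx21 rose by 1.83 ± 0.28, Il3 by 1.77 ± 0.49, Gpr83 by 1.61 ± 0.20 and Sema7a by 1.58 ± 0.17. Of 24 G2 and M phase genes 10 fell (18 adjusted over the list alone) by a list median of -0.66, with Kif11 at -1.47 ± 0.31 and Top2a at -1.47 ± 0.31 (adjusted p = 2.2e-16; 0.0406 with an estimated correlation; 2 of 2 arrays below all anti-CD3 arrays). Cytokines rose in 4 of 20 with Lta at 1.29 ± 0.20 and Lif at 1.21 ± 0.17. The Treg signature had 1 member up and 4 down, with Itgae at -1.02 ± 0.22 and Fgl2 at -0.95 ± 0.23 after Klrg1 and Gpr83. When adjusted over the list alone 6 cytokines were up and 1 down, and of the signature 4 were up and 9 down. Array 1 of this group had the lowest upper quartile of all arrays, 290 units. Altogether limma called 53 genes up and 183 down, or 94 up and 125 down after cyclic loess and 32 and 94 with only the groups compared. The total of 236 fell to 46 without anti-ICOS replicate 1, to 152 and 131 without anti-CD3 replicates 3 and 4, and to 43 (21 up and 22 down) without the early Treg arrays numbered 1, a choice made after seeing the data. Without anti-ICOS replicate 1 the calls of Ccna2, Kif11, Top2a, Atp6v0d2, Ccr2, Itgae, Fgl2 and Il3 ended (adjusted p up to 0.935, for Il3, whose change was then 0.61), whereas those of Klrg1, Tbx21, Gpr83 and Sema7a held.

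In late Treg anti-ICOS, like anti-CD28, was followed by higher S phase and ribosome biogenesis genes. The retinoid binding protein Crabp2 rose by 2.63 ± 0.20, the T-box factor Eomes by 2.56 ± 0.23, Ccr8 by 2.47 ± 0.31 and Tbx21 by 2.28 ± 0.28. The S phase list rose in 27 of 28 members (median 0.97) and ribosome biogenesis in 24 of 24 (median 1.14), with Tipin at 1.57 ± 0.23 and Nop58 at 1.87 ± 0.29. Of 24 G2 and M phase genes 4 rose and 1 fell, Bub1 first at 1.20 ± 0.37 (median 0.08; adjusted p = 0.241, but 0.0329 after cyclic loess and 0.0244 without the filter). Immediate early genes rose in 14 of 25 with Atf3 at 1.71 ± 0.22, Myc at 1.43 ± 0.30 and Irf4 at 1.33 ± 0.15 (adjusted p = 1.24e-07; adjusted p = 0.0519 with an estimated correlation), and amino acid genes in 12 of 17 with Psat1 at 1.71 ± 0.15. Of the costimulatory list 5 rose and 5 fell, Cd200 at 1.04 ± 0.18, Pdcd1 at -0.94 ± 0.18, Ctla4 at -0.86 ± 0.19 and Icos itself at -0.83 ± 0.14. Adjusted over the list alone 28 S phase, 24 ribosome biogenesis, 3 G2 and M phase, 16 immediate early and 12 amino acid genes were up, and of the costimulatory list 5 up and 6 down. Foxp3 fell by 0.37. The test by limma called 1744 genes up and 1112 down. Without anti-ICOS replicate 1 the calls of Bub1, Ctla4 and Foxp3 ended (adjusted p = 0.116 for Bub1 and 0.0809 for Ctla4), that of Foxp3 also without replicate 2 (adjusted p up to 0.114).

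The direct contrast of anti-ICOS with anti-CD28 asks where these costimuli differ. In late Tconv anti-ICOS left more Eomes (3.12 ± 0.24), the chemokine Xcl1 (2.85 ± 0.41), Nkg7 (2.28 ± 0.32) and Il3 (2.27 ± 0.52), and less Bnip3 (-2.67 ± 0.28), Scd1 (-2.34 ± 0.36) and Egln3 (-2.23 ± 0.34). Members lower with anti-ICOS were 19 of 28 in S phase, 19 of 24 in G2 and M phase, 11 of 14 in glycolysis with the glucose transporter Slc2a3 at -1.92 ± 0.31, and 6 of 17 in cholesterol synthesis with Lss at -1.12 ± 0.19 (23, 23, 13 and 10 adjusted over each list alone). Of 18 NF-kappaB targets 3 were higher with Tnfaip3 at 1.01 ± 0.21, and of 5 CD8 and NK markers 3 were higher, Eomes, Nkg7 and Klrd1 (1.15 ± 0.30), genes that activated CD4 cells also express (4 and 3 adjusted over the list alone). Over all genes limma called 178 genes higher and 464 lower, but 7 and 11 with only the groups compared. The total of 642 fell to 287 without anti-CD28 replicate 3 and to 317 without anti-ICOS replicate 2. Without anti-CD28 replicate 3 Scd1 and Slc2a3 were at -1.37 and -1.23. The calls of Il3 and Tnfaip3 ended without anti-ICOS replicate 2 (adjusted p = 0.0635 and 0.0616), and that of Klrd1 without anti-CD28 replicate 3 or anti-ICOS replicate 1 (up to 0.16).

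Elsewhere these differed in fewer genes. In early Tconv limma called 3 genes higher with anti-ICOS, Prnp at 0.92 ± 0.16, Lif at 0.90 ± 0.17 and Trib1 at 0.75 ± 0.14. In late Treg 11 were higher and 8 lower, with Crabp2 at 1.41 ± 0.21, Eomes at 1.38 ± 0.24, Sema7a at 1.20 ± 0.17 and the immediate early gene Nr4a1 at 1.02 ± 0.20 among the higher. Those lower included Prdm1 (Blimp-1) at -1.04 ± 0.21, Slamf6 at -0.96 ± 0.17 and Icos at -0.84 ± 0.14. The immediate early list lay higher by a median of 0.37 (1 called, 6 adjusted over the list alone; adjusted p = 6.79e-17). In early Treg 22 were higher and 91 lower, with Klrg1 at -2.19 ± 0.25, Ccr2 at -1.59 ± 0.42 and Gzmb at -1.45 ± 0.39. There the Treg signature had 3 members lower and the G2 and M phase list 2 (6 and 5 adjusted over the list alone), and their adjusted p of 0.00995 and 0.00118 became adjusted p = 0.57 and 0.896 with an estimated correlation. Cyclic loess moved all genes of the early Treg contrast by a median of 0.10 and left 6 higher and 43 lower, with list medians of -0.17 and -0.47, while 88 were higher and 86 lower without the floor. With only the groups compared limma called 0, 0 and 1 genes in early Tconv, late Treg and early Treg (352 and 203 at an unadjusted p under 0.05 where 0). The counts rested on single arrays: 3 became 0 without anti-ICOS replicate 1 or 2 and 6 without anti-CD28 replicate 2 of early Tconv. In late Treg 19 became 2 and 11 without anti-ICOS replicates 1 and 2 and 12 without anti-CD28 replicate 2. In early Treg 113 became 5 and 543 without anti-ICOS replicates 1 and 2 and 6 and 40 without anti-CD28 replicates 2 and 3. Each gene named for late Treg lost its call without anti-ICOS replicate 1 (adjusted p from 0.16 to 0.855, with Slamf6 then at -0.55), and for early Treg Ccr2 and Gzmb did so without anti-ICOS replicate 1 or anti-CD28 replicate 1 or 2 (up to 0.535 and 0.647).

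Anti-BTLA was compared with anti-CD3 only to ask what an antibody to this inhibitory receptor does; the labels do not say whether it engages or blocks. In late Tconv it was followed by higher proliferation genes: Socs2 rose by 1.85 ± 0.24, Ccna2 by 1.84 ± 0.29, the mitotic kinesin Kif11 by 1.62 ± 0.27 and Bub1 by 1.57 ± 0.33. S phase genes rose in 24 of 28 members by a median of 0.73, with Rrm2 at 1.44 ± 0.21, and G2 and M phase genes in 20 of 24 by a median of 1.12 (28 and 22 adjusted over the list alone; adjusted p = 8.24e-62 and 2.69e-67; 3 of 3 arrays above all anti-CD3 arrays for each). IL-2 and STAT5 targets rose in 5 of 19 (9 adjusted over the list alone), with Cish at 1.17 ± 0.17 and Il2rb at 0.83 ± 0.13. Of 22 quiescence genes Il7r fell by 1.61 and Txnip by 0.68, while Igfbp4 rose by 1.04 ± 0.19 (7 down and 1 up adjusted over the list alone). In all, limma called 225 genes up and 27 down, 397 in total with replicate number as a block and 101 with only the groups compared, and the total of 252 fell to 152 without anti-BTLA replicate 3. The call of Txnip ended without anti-BTLA replicate 1 or 3 or anti-CD3 replicate 3 or 4 (adjusted p up to 0.208).

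In early Tconv anti-BTLA raised Sema7a by 1.05 ± 0.15, Slamf7 by 0.80 ± 0.18, the lipid transporter Mfsd2a by 0.79 ± 0.15 and Gfi1 by 0.77 ± 0.14, and Heatr5a fell by 0.58 ± 0.13. There limma called 15 genes up and 1 down, 133 in total with replicate number as a block and 0 with only the groups compared (980 at an unadjusted p under 0.05). Ribosome biogenesis shifted by a median of 0.39 with 0 members called by limma and 14 adjusted over the list alone (adjusted p = 5.36e-22), cholesterol synthesis by 0.37 with 0 and 7, and the immediate early list by 0.32 with Irf4 called at 0.61 ± 0.14 and 7 adjusted over the list alone. Of all genes 681 reached an unadjusted p under 0.05. The count of 16 fell to 2, 10 and 1 without anti-BTLA replicates 1, 2 and 3, and to 2, 2 and 7 without anti-CD3 replicates 2, 3 and 4. In late Treg Irf4 was the 1 gene called, at 0.74 ± 0.14, with 0 called down and 775 at an unadjusted p under 0.05 with limma. Ribosome biogenesis shifted there by a median of 0.34 (15 members adjusted over the list alone; adjusted p = 1.48e-19), heat shock genes by 0.35 (5; 1.56e-09) and S phase genes by 0.20 (4; 2.08e-10), with 3 of 3 arrays above all anti-CD3 arrays in each. That count of 1 became 0 without anti-BTLA replicate 1 or 3 or anti-CD3 replicate 2, 3 or 4, and 6 and 8 without anti-BTLA replicate 2 and anti-CD3 replicate 1. In early Treg limma called 0 genes, with 263 at an unadjusted p under 0.05. Of the early Tconv genes named, Sema7a alone kept its call without each array in turn; the others reached an adjusted p of up to 0.503.

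In the main fit anti-CTLA-4, anti-PD-1 and anti-CD80 were followed by no gene that passed limma's test in any of 12 comparisons with anti-CD3 only. In early and late Tconv and early and late Treg an unadjusted p under 0.05 was reached by 85, 41, 129 and 1035 genes with anti-CTLA-4, by 257, 58, 173 and 676 with anti-PD-1, and by 585, 1174, 161 and 1177 with anti-CD80. Other settings called a few genes: 5 for anti-CD80 in late Tconv without the floor and 5 after cyclic loess, 3 with 32 units added, and 1 for anti-PD-1 in late Treg without the floor. Lists did shift with anti-CD80. In late Tconv S phase genes lay higher by a median of 0.42, with 0 called by limma and 19 of 28 adjusted over the list alone and 2 of 2 arrays above all anti-CD3 arrays (adjusted p = 2.52e-22), Rrm2 first at 0.96 ± 0.24. G2 and M phase genes lay higher by 0.51, with 12 of 24 adjusted over the list alone and Ccna2 first at 1.18 ± 0.33 (adjusted p = 3.28e-15; adjusted p = 0.0877 with an estimated correlation). In late Treg ribosome biogenesis lay higher by 0.38 with anti-CD80 (9 adjusted over the list alone; adjusted p = 4.78e-13; adjusted p = 0.0506 with an estimated correlation), Nop58 first at 0.96 ± 0.29. The same list lay higher by 0.25 with anti-CTLA-4 (1 adjusted over the list alone; adjusted p = 0.000259; adjusted p = 0.757 with an estimated correlation) and by 0.11 with anti-PD-1 (adjusted p = 0.024; adjusted p = 0.775 with an estimated correlation, and 0.382 after cyclic loess). With anti-CD80 the count of 0 became 27, 19 and 1 in late Tconv, late Treg and early Tconv without anti-CD3 replicate 1. With anti-CTLA-4 it became 1 in early Treg without anti-CTLA-4 replicate 2.

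**Figure D3:**
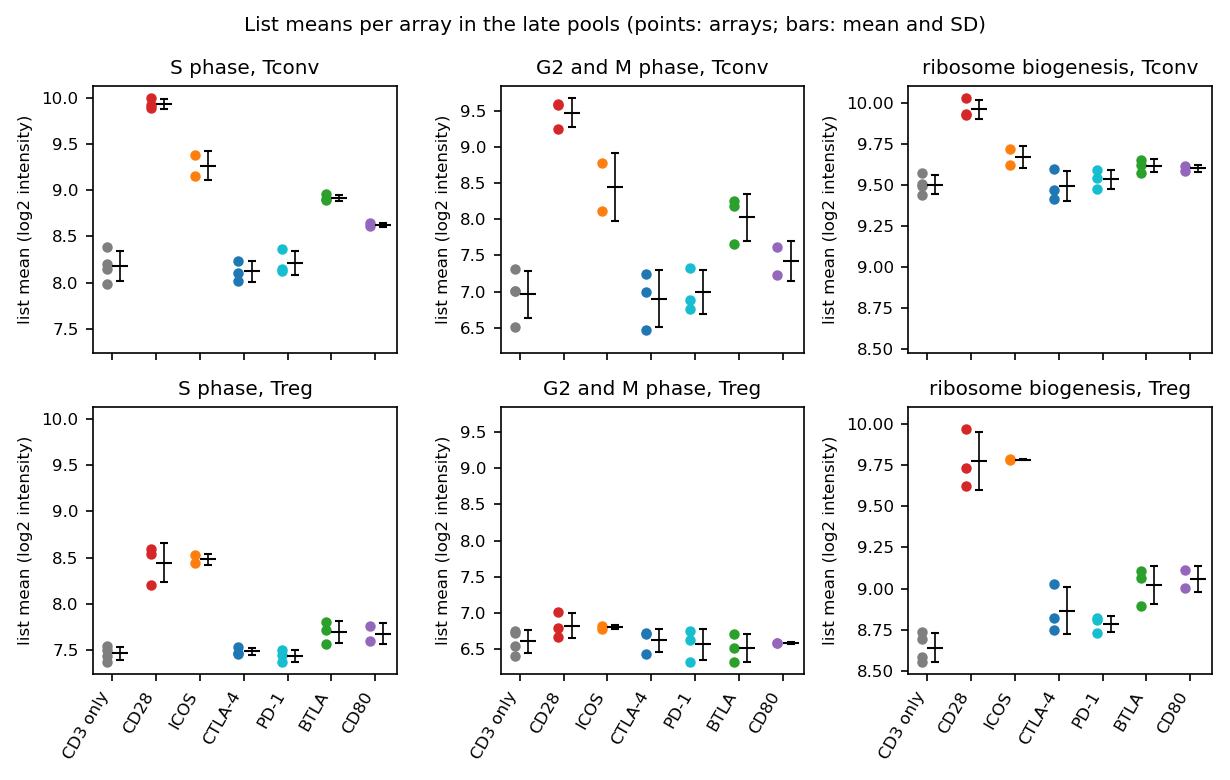
Mean log2 intensity of the S phase, G2 and M phase and ribosome biogenesis lists (vertical axes, 1 scale per list) in each late array of Tconv and Treg given anti-CD3 only or with another antibody (horizontal axis). Points are arrays and bars the group mean and SD; the anti-BTLA arrays of Tconv lie above all anti-CD3 arrays in the first 2 lists, and in Treg the G2 and M phase means of all groups lie in 1 narrow range.

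Likeness to the anti-CD28 effect was measured by correlation across genes, which are not independent replicates, so no p is given. In late Treg anti-ICOS and anti-CD28 changes correlated with r = 0.922, and with 0.826 when the shared anti-CD3 arrays were split between the antibodies. The values were 0.796 and 0.711 for anti-ICOS and 0.833 and 0.674 for anti-BTLA in late Tconv, 0.784 and 0.556 for anti-BTLA in late Treg, 0.535 and 0.441 for anti-CD80 in late Tconv, and 0.643 and 0.484 for anti-CD80 in late Treg. For these 6 cases unchanged groups simulated with shared controls gave mean correlations from 0.314 to 0.364, with upper bounds (middle 95%) from 0.767 to 0.881. With shared controls anti-ICOS in late Treg alone lay above its bound, 0.831. Covariances in the order above were 0.155, 0.139, 0.0893, 0.0535, 0.0679 and 0.0525, against simulated means of 0.0106, 0.0144, 0.012, 0.0115, 0.0125 and 0.0111. All but that of anti-BTLA in late Treg lay above their simulated bound. Deviations shared by number, which split controls keep, may add to all these values. In early Tconv anti-ICOS reached 0.767 and 0.507, and anti-BTLA 0.673 and 0.316, below the simulated bounds of 0.847 and 0.835. Anti-ICOS in early Treg reached 0.21 and 0.021, and anti-CTLA-4 in late Tconv 0.028 and -0.112. Of 225 genes raised by anti-BTLA in late Tconv 222 were also raised by anti-CD28 (43.1 for independent lists, ignoring shared controls). All 27 lowered genes were shared (2.76). In late Treg 1534 genes were raised by both anti-ICOS and anti-CD28 (305 for independent lists) and 632 lowered by both (89.4), with 0 in opposite directions. In late Tconv 517 of the 562 genes raised by anti-ICOS were shared (108), with 8 in opposite directions.

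Whether an antibody strengthened or weakened the anti-CD3 response itself was scored on genes induced and repressed at least 2-fold in the other cell type. In late Treg the score lay higher with anti-ICOS than with anti-CD3 only by 0.49, which is 35.3% of the response to anti-CD3, and with anti-CD28 by 0.28 or 20.2%, with every antibody array above all anti-CD3 arrays. In late Tconv it lay lower by -0.51 (-28.1%) with anti-CD28 and by -0.45 (-24.8%) with anti-ICOS, with every antibody array below all anti-CD3 arrays. The exact two-sided permutation p values were 0.0667, 0.0571, 0.0286 and 0.133, and the smallest that the arrays allow is 0.0286 for 3 arrays against 4 and 0.0667 for 2 against 4. Adjusted over all 24 comparisons the smallest exact p was 0.369, and the smallest adjusted p from limma's fry was 0.0747, for anti-ICOS in late Treg. The exact test had little room to pass after this adjustment. With genes of the same cell type, chosen from the same anti-CD3 arrays, the late Treg shifts were -0.51 with anti-ICOS and -0.36 with anti-CD28, and those of late Tconv -0.01 each.

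Treg and Tconv responses were compared by testing the difference of their effects. At early time anti-CD3 raised the CD30 ligand Tnfsf8 more in Treg than in Tconv by 2.08 ± 0.25, Rnf157 by 1.99 ± 0.22, Epas1 by 1.98 ± 0.26 and Il10 by 1.85 ± 0.44. Effects were lower in Treg for Akr1c18 (-2.88 ± 0.33), Sema7a (-2.65 ± 0.21), Il2ra (-2.24 ± 0.28), Hivep3 (-2.13 ± 0.35) and Irf4 (-1.90 ± 0.19). The immediate early list had 2 members higher and 2 lower, Egr2 at -1.49 ± 0.32, Fos at 1.32 ± 0.28 and Junb at 1.13 ± 0.30 after Irf4 (6 and 6 adjusted over the list alone). IL-2 and STAT5 targets and ribosome biogenesis each had 2 members lower, with Socs1 at -0.95 ± 0.24 and Polr1b at -0.90 ± 0.22 (3 and 5 adjusted over the list alone). Both list calls (adjusted p = 0.0127 and 8.09e-09) were lost with an estimated correlation (adjusted p = 0.228 for each). Altogether limma called 91 genes higher and 45 lower. The calls of Junb, Socs1, Polr1b, Fos and Il10 ended without 1 or more single arrays of the 4 groups (adjusted p up to 0.18, 0.139, 0.107, 0.0547 and 0.0503).

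All late differences may reflect time, as only Tconv pools hold 48 h. With anti-CD28 mitotic genes differed most. All 24 G2 and M phase genes had a lower effect in Treg, by a median of -2.36, with Hmmr at -3.19 ± 0.30 and Ccnb2 at -3.14 ± 0.28 (adjusted p = 1.98e-86; 2.47e-07 with an estimated correlation). The S phase list had 16 of 28 members lower with Rrm2 at -1.83 ± 0.30, and IL-2 and STAT5 targets 6 of 19 with Socs2 at -2.88 ± 0.35 and Il2rb at -1.87 ± 0.18. Ribosome biogenesis had 13 of 24 members higher in Treg with Npm1 at 1.01 ± 0.28 (20 adjusted over the list alone), and NF-kappaB targets 8 of 18 with the apoptosis inhibitor Cflar at 1.04 ± 0.31 (14 adjusted over the list alone). Adjusted over the list alone 24 G2 and M phase, 17 S phase and 10 IL-2 and STAT5 genes were lower. In all limma called 189 genes higher and 499 lower. At early time 1 gene passed, Chst15 at -0.70 ± 0.13, and 261 (2.23%) had an unadjusted p under 0.05. The cytokine list median was -0.34 (camera adjusted p = 1.24e-05 at the preset correlation), with 0 members called by limma and 0 over the list alone. That count of 1 became 0 without anti-CD28 replicate 1 or 2 of Treg, anti-CD3 replicate 1 or 4 of Treg or anti-CD3 replicate 3 or 4 of Tconv, and 2 without anti-CD28 replicate 3 or anti-CD3 replicate 2 of Tconv. The late calls of Cflar and Npm1 ended without any of several arrays, anti-CD28 replicate 3 of either cell type among them (adjusted p up to 0.096 and 0.105).

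For anti-ICOS late, G2 and M phase genes had a lower effect in Treg in 17 of 24 members, with Ccnb2 at -2.93 ± 0.32 and Plk1 at -2.28 ± 0.28. Ribosome biogenesis had a higher one in 17 of 24 (23 adjusted over the list alone), with Nop58 at 1.84 ± 0.41. Of the Treg signature 8 of 27 had a lower effect, among them Lrrc32 at -1.73 ± 0.27, Entpd1 (CD39) at -1.69 ± 0.26 and Ctla4 at -1.20 ± 0.27 (adjusted p = 7.16e-09; 0.00337 with an estimated correlation). Of the NF-kappaB targets 4 of 18 had a higher one with Cflar at 1.16 ± 0.35. Adjusted over the list alone 18 G2 and M phase and 12 Treg signature genes were lower and 6 NF-kappaB targets higher. Over all genes limma called 224 genes higher and 224 lower, or 155 and 314 after cyclic loess, and the total of 448 fell to 182 without anti-ICOS replicate 1 of Tconv and to 207 without anti-ICOS replicate 1 of Treg. At early time 4 genes had a lower effect in Treg, Klrg1 at -2.37 ± 0.34, Pdcd1 at -1.61 ± 0.26, Prnp at -1.30 ± 0.22 and Cxcr3 at -1.21 ± 0.23, or 3 higher and 6 lower after cyclic loess. The early G2 and M phase list lay lower by -0.51 with 0 members called by limma and 3 adjusted over the list alone (adjusted p = 9.16e-06; adjusted p = 0.405 with an estimated correlation). The count of 4 became 2 without anti-ICOS replicate 1 of Tconv, 7 without anti-CD3 replicate 2 of Treg and 19 without anti-ICOS replicate 2 of Treg. Without anti-ICOS replicate 1 of Treg the late call of Ctla4 (adjusted p = 0.1) and the early call of Prnp (0.068) ended, without anti-ICOS replicate 1 of Tconv those of Pdcd1 and Cxcr3 (0.0586 and up to 0.137) and of Cflar (up to 0.426).

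For anti-BTLA late, 46 genes had a lower effect in Treg and 0 a higher one, led by Ccna2 at -2.05 ± 0.41, Nusap1 at -1.76 ± 0.31 and Kif11 at -1.75 ± 0.39. They held 12 of 24 G2 and M phase genes (22 adjusted over the list alone; adjusted p = 4.68e-75) and 2 of 28 S phase genes, Rrm2 at -1.35 ± 0.30 and Cdc45 at -0.71 ± 0.16 (15 adjusted over the list alone). Without anti-BTLA replicate 3 of Tconv, anti-CD3 replicate 2 of Tconv or anti-BTLA replicate 3 of Treg the count was 25, 26 or 28. No gene passed limma's test of the difference for anti-CTLA-4, anti-PD-1 and anti-CD80 at either time or for anti-BTLA early. An unadjusted p under 0.05 was reached early and late by 80 and 453 genes with anti-CTLA-4, by 203 and 392 with anti-PD-1 and by 345 and 1089 with anti-CD80, and early by 519 with anti-BTLA. For anti-BTLA early the count became 2 without anti-BTLA replicate 3 of Treg, and for anti-CD80 early 4 without anti-CD80 replicate 2 of Treg. The calls of Kif11, Rrm2 and Cdc45 ended without any of several single arrays, anti-CD3 replicate 2 of Tconv among them (adjusted p up to 0.133, 0.131 and 0.229).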

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

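Of the tests below, those of differences between cell types were planned and the ceiling test was set before its result was seen. All other weighing tests and the counts of other splits were chosen after the results were seen.

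By limma's test effects differed between Treg and Tconv in 136 genes for anti-CD3 early, 1 for anti-CD28 early and 4 for anti-ICOS early. Late counts were 688 for anti-CD28, 448 for anti-ICOS and 46 for anti-BTLA, where pool times differ too. Median differences of lists called by camera (Treg minus Tconv) were -2.36 for G2 and M phase, -0.73 for S phase, 0.71 for ribosome biogenesis, 0.64 for NF-kappaB targets and -0.54 for IL-2 and STAT5 targets with anti-CD28 late, and -0.34 for cytokines with anti-CD28 early. With anti-ICOS late they were -1.20 for G2 and M phase, 0.94 for ribosome biogenesis, -0.54 for the Treg signature and 0.36 for NF-kappaB targets. With anti-ICOS early G2 and M phase lay at -0.51. With anti-BTLA late the medians were -1.22 for G2 and M phase and -0.53 for S phase, and with anti-CD3 early -0.16 for IL-2 and STAT5 targets and -0.40 for ribosome biogenesis. Calls for anti-ICOS early and anti-CD3 early were lost with an estimated correlation (adjusted p = 0.405, and 0.228 for each). The cytokine list had 0 members called.

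The first pattern is the rise of G2 and M phase genes with anti-CD28 in late Tconv, far larger than in late Treg. A ceiling of the array is excluded, since with anti-CD28 the late Treg list mean lay below late Tconv by -2.65 (SDs 0.17 and 0.20). A limit of Treg or of 20 h was not tested. Cyclic loess ran on the authors' normalized values, so it cannot test their normalization (24 of 24 calls kept, median difference -2.38). The 48 h lysate cannot be told apart from cell type as source of the difference of -2.36, as no Treg pool holds 48 h. A slower entry of Treg into mitosis may also contribute and is untested.

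The second pattern is the fall of G2 and M phase genes, with Klrg1 and Ccr2, in early Treg given anti-ICOS. A low signal on the array numbered 1 is argued against, since the list median was -0.71 in the array numbered 2 alone and -0.58 in the array numbered 1 alone. A difference that goes with the numbers 1 and 2 is argued against by anti-CD80, which has the same numbers and a median of 0.015, against -0.66 for anti-ICOS. The call counts still rest on the array numbered 1, as 46 genes were called without it. A true effect of ICOS on early Treg, for example on the cells recovered in the sort, may remain and was not tested.

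The third pattern is that anti-BTLA in late Tconv moved genes the way anti-CD28 did. A difference that goes with the numbers 1 to 3 is argued against by S phase medians of 0.015 with anti-PD-1 and -0.06 with anti-CTLA-4 against 0.73 with anti-BTLA, and a single array is argued against, since 3 of 3 anti-BTLA arrays had an S phase mean above all anti-CD3 arrays (lowest 8.89, highest anti-CD3 array 8.39). Cells of the anti-CD28 culture mixed in would need 1 share of anti-CD28 signal for all genes and are argued against as the whole cause: it was higher for S phase than for glycolysis genes by 16.3 percentage points (SD 4.23 between arrays), although without anti-CD28 replicate 3 the 12.2 (SD 6.2) is under 2 SD, and G2 and M phase genes (higher by 0.24 to 19.9, or by -6.01 to 17.3 without that replicate) and cholesterol synthesis genes (share 18.4%, SD 12.8) do not decide. Carried-over anti-CD28 antibody cannot be told apart from an effect of anti-BTLA, since a lower dose need not move all genes in proportion and either would give the glycolysis share of 11% (SD 4.46). Release from BTLA inhibition by an antibody that blocks rather than engages the receptor may be an explanation and was not tested.

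Several measures moved in opposite directions in a pair of settings in every array, against the mean of the anti-CD3 arrays and partly within their range; these differences were not tested, and no activation shift passed its own test. The activation score, for which each cell type uses genes of the other, moved in late Tconv and late Treg by -0.51 and 0.28 with anti-CD28, -0.45 and 0.49 with anti-ICOS, -0.26 and 0.062 with anti-BTLA, and -0.35 and 0.18 with anti-CD80, and in early cells by -0.18 and 0.01 with anti-CD80. Its genes differ between cell types, and in late Treg these 4 signs turned with genes of the same cell type. Anti-ICOS and anti-CD80 hold only numbers 1 and 2. List means moved early and late with anti-CD28 in Tconv by 0.47 and -0.20 for immediate early genes, 0.27 and -0.14 for NF-kappaB targets, and -0.14 and 2.52 for G2 and M phase. In Treg they moved with anti-CD28 by -0.10 and 0.98 for S phase and -0.31 and 0.22 for G2 and M phase. With anti-ICOS the G2 and M phase mean moved by -0.22 and 1.48 in Tconv and -0.78 and 0.19 in Treg, and the S phase mean by -0.33 and 1.02 in Treg. In Treg the ribosome biogenesis mean moved by -0.14 and 0.23 with anti-CTLA-4, and the S phase mean by -0.066 and 0.24 with anti-BTLA.

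Single arrays stood apart from the other 3 in groups given anti-CD3 only, by Dixon's ratio of the gap to the range, which chance gives in about 1 group in 20. Of 235 gene values tested 17 did, of 45 list values 1 and of 4 activation scores 1. In early Tconv these were Egr3 (ratio 0.869), Rcan3 (0.903) and Socs1 (0.911) for replicate 1, Hivep3 (0.878), Rel (0.836), Tnfrsf9 (0.903) and the activation score (0.834) for replicate 2, and Nfkbid (0.864) for replicate 3. In late Tconv they were Il7r (0.840) for replicate 1, Cish (0.830) and Kif11 (0.864) for replicate 2 and the glycolysis list (0.941) for replicate 4. In early Treg they were Irf4 (0.833), Nr4a3 (0.840) and Usp18 (0.867) for replicate 1, Itgae (0.907) for replicate 3 and Tnfsf8 (0.873) for replicate 4, and in late Treg Phlpp1 (0.906) and S1pr1 (0.967) for replicate 2.

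Other splits of the same arrays were counted for comparisons with at least 3 arrays per group. For anti-CD3 in early and late Tconv and early and late Treg only 1 of 35 splits, the real one, gave as many genes: 2007, 2006, 2082 and 1120 against at most 1834, 1223, 980 and 443. The same held for anti-CD28 in these settings (84, 3439, 20 and 2989 against at most 51, 2415, 8 and 1883) and for anti-BTLA in late Tconv (252 against 225). Unadjusted, chance splits are excluded at a share under 0.05 for anti-CD3 alone. The others ignore shared numbers, whose pairs in late Treg given anti-CD28 had r from 0.001 to 0.538. For anti-BTLA in early Tconv 2 of 35 splits (16 real, 16 highest other) and in late Treg 3 of 35 (1 and 5) gave as many, so chance cannot be excluded. The 10 splits of the resting arrays are too few for a share under 0.05 (1 gave as many; 1834 real, 1526 highest other). Where limma called 0 genes all 35 splits gave as many, with at most 0, 1, 3 and 1 genes for anti-CTLA-4 in early and late Tconv and early and late Treg, 0 and 2 for anti-PD-1 in early and late Tconv, 0 in late Treg, and 1 for anti-BTLA in early Treg. In comparisons taken as paired by number only 8 splits part all 3 pairs, too few for a share under 0.05. Among them the highest other counts were 4 for anti-CD28 in early Tconv, 1616 in late Tconv and 0 in early Treg, and 2 and 91 for anti-BTLA in early and late Tconv. Splits that leave a pair together reached up to 51, 2415, 8, 16 and 225.

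For differences of effects 100 splits were drawn with a fixed seed. As many genes were called by 11 of 100 for anti-CD3 early (136 real, 1970 highest other), 15 for anti-CD28 early (1 and 28), 12 for anti-CD28 late (688 and 2509) and 6 for anti-BTLA late (46 and 271), so chance was not excluded. For differences with 0 genes all 100 gave as many, with a highest other of 0 and 0 for anti-CTLA-4 early and late, 4 for anti-PD-1 late and 20 for anti-BTLA early. Splits that call several times the real count point to a structure of the samples: separate splits do not cancel the effect common to both cell types. Splits were then drawn again with that effect removed. As many genes were then called by 3 of 100 for anti-CD3 early (highest other 1580, again a structure of the samples), 1 for anti-CD28 late (250), 1 for anti-BTLA late (10) and 7 for anti-CD28 early (2). These splits ignore the cultures that both cell types share and the pairs by number, so they exclude chance for none. In splits added last, with arrays of the same number in both cell types kept together, only 1 of 35 splits, the real one, gave as many for anti-CD3 early (136, highest other 61). This excludes chance only if a number marks a culture, which the labels do not say.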

How the results depend on the processing

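The alternatives were planned, except leaving out the early Treg arrays numbered 1, the upper quartile as a covariate and the replicate block for lists and correlations, which were chosen after seeing the data. No called gene among those examined changed direction, nor did a reported list with a call, run for no floor, cyclic loess, 32 units added and the replicate block. Among values without a call signs changed for some activation shifts, the Treg signature with anti-ICOS in early Treg and some correlations with the anti-CD28 effect, none above 0.311. Where not said otherwise, the cause of a change was not tested. Signal over background limits dim genes most: 8046 genes under the floor were tested only without it, and without it every adjustment runs over more genes.

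Without the floor, counts of called genes were 1 for anti-PD-1 in late Treg, 6 for anti-BTLA in early Tconv, 5 for anti-CD80 in late Tconv, 174 for anti-ICOS minus anti-CD28 in early Treg and 0 for the anti-CD28 early difference between cell types (limma; 456 at an unadjusted p under 0.05). The G2 and M phase list of late Treg, with medians of 0.0853 with anti-CD28 and 0.0793 with anti-ICOS, was then called. After cyclic loess the counts were 7 for anti-BTLA in early Tconv, 5 for anti-CD80 in late Tconv, 49 for anti-ICOS minus anti-CD28 in early Treg and 9 for the anti-ICOS early difference. The same G2 and M phase lists were called (medians 0.145 and 0.188), while cytokines (0.308) and anergy genes (0.193) in early Tconv given anti-CD3 and ribosome biogenesis with anti-PD-1 in late Treg (0.0578) lost their calls. With 32 units added, 3 genes were called for anti-CD80 in late Tconv and 3 for the anti-CD28 early difference, and the activation shift of anti-ICOS in early Treg became -0.0004.

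A fit with only the groups compared has fewer arrays to estimate the spread. It called 1204 and 458 genes for anti-CD3 in early and late Treg, 563 for resting cells, 2 for anti-CD28 in early Tconv, 65, 373 and 126 for anti-ICOS in early Tconv, late Tconv and early Treg, and 0, 101 and 0 for anti-BTLA in early Tconv, late Tconv and late Treg. For anti-ICOS minus anti-CD28 it called 0 and 18 in early and late Tconv and 1 and 0 in early and late Treg, and for the differences between cell types 0 for anti-CD28 early, 213 for anti-ICOS late and 10 for anti-BTLA late. Where limma called 0 here, an unadjusted p under 0.05 was reached by 980 and 894 genes for anti-BTLA in early Tconv and late Treg, 352 and 203 for anti-ICOS minus anti-CD28 in early Tconv and late Treg, and 481 for the anti-CD28 early difference.

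The replicate block raised most counts: 4322, 4097, 3882 and 3469 for anti-CD3 in early and late Tconv and early and late Treg, 3173 for resting cells, 172 and 66 for anti-CD28 in early Tconv and early Treg, 276, 1279 and 622 for anti-ICOS in early Tconv, late Tconv and early Treg, 1 for anti-PD-1 in late Treg, 133, 397 and 43 for anti-BTLA in early Tconv, late Tconv and late Treg, and 25, 1 and 16 for anti-CD80 in late Tconv, early Treg and late Treg. For anti-ICOS minus anti-CD28 it gave 990, 946 and 46 in late Tconv, early Treg and late Treg, and for the differences 225 (anti-CD3 early), 3 and 1055 (anti-CD28 early and late), 102 and 905 (anti-ICOS) and 82 (anti-BTLA late). Cytokines (0.188) and anergy genes (0.214) in early Tconv given anti-CD3 were not called with the block, and the Treg signature of anti-ICOS in early Treg moved to -0.012. The activation shift moved to 0.0015 for anti-BTLA in early Tconv and 0.0393 for anti-CTLA-4 in early Treg. The other list and gene calls were the same with the block, except 1 gene that gained a call. With the random replicate block the counts were 2808 for resting cells, 220 for anti-CD3 early, 3 for anti-CD28 early, 81 and 836 for anti-ICOS early and late and 86 for anti-BTLA late.

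Activation genes of the same cell type gave shifts of 0.0317 and 0.0763 for anti-BTLA in early and late Tconv. In early Treg they gave -0.121 for anti-CD28, -0.311 for anti-ICOS, 0.0625 for anti-PD-1 and -0.0511 for anti-CD80, and in late Treg -0.362 for anti-CD28, -0.506 for anti-ICOS, -0.021 for anti-CTLA-4, -0.0755 for anti-BTLA and -0.0043 for anti-CD80. Without the early Treg arrays numbered 1 the counts were 43 for anti-ICOS in early Treg, 3 for anti-ICOS minus anti-CD28 in early Treg and 0 for the anti-CD28 early difference (limma; 308 at an unadjusted p under 0.05). With the upper quartile as a covariate 244 genes were called for anti-ICOS in early Treg.

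With each array left out in turn, counts ranged for anti-CD3 from 1153 to 2290 in early Tconv, 1215 to 2074 in late Tconv and 657 to 1135 in late Treg, and for resting cells from 1157 to 2103. For anti-CD28 they ranged from 28 to 117 in early Tconv, 4 to 24 in early Treg and 1748 to 2899 in late Treg. For anti-ICOS they ranged from 46 to 180 in early Tconv, 266 to 957 in late Tconv and 46 to 327 in early Treg. For anti-BTLA they ranged from 1 to 18 in early Tconv, 152 to 285 in late Tconv and 0 to 8 in late Treg, for anti-CD80 from 0 to 1 and 0 to 27 in early and late Tconv and 0 to 2 and 0 to 19 in early and late Treg, and for anti-CTLA-4 in early Treg from 0 to 1. For anti-ICOS minus anti-CD28 they ranged from 0 to 6 and 287 to 718 in early and late Tconv and 5 to 543 and 2 to 16 in early and late Treg. The differences ranged from 0 to 2 for anti-CD28 early, 2 to 19 and 182 to 476 for anti-ICOS early and late, 0 to 2 and 25 to 66 for anti-BTLA early and late and 0 to 4 for anti-CD80 early. The activation shift ranged from -0.128 to 0.112 for anti-BTLA and -0.178 to 0.0672 for anti-CD28 in early Tconv, from -0.216 to 0.0702 for anti-CTLA-4 and -0.255 to 0.101 for anti-PD-1 in late Tconv, and from -0.009 to 0.0371 for anti-CD80, -0.0446 to 0.0015 for anti-PD-1 and -0.003 to 0.0526 for anti-ICOS in early Treg. Where leaving out an array took a count to 0 with limma, between 169 and 792 genes still had an unadjusted p under 0.05. The correlation of anti-CD80 with anti-CD28 in late Treg ranged from 0.446 to 0.692.

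Of 314 gene results examined, 11 lost their call without the floor, 10 after cyclic loess, 1 with 32 units added and 68 with only the groups compared. Of 62 that involve early Treg, 17 lost it without the arrays numbered 1. With single arrays left out, 201 of 2348 gene results lost their call and 2 gained one, none with a change of direction.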

Other observations

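Transcripts of the molecules that the antibodies bind had the following levels in cells given anti-CD3 only. Cd28 was at 11.91 ± 0.14 (SD, 4 arrays) early and 11.85 ± 0.09 late in Tconv and at 11.58 ± 0.14 and 11.23 ± 0.13 in Treg. Icos was at 11.77 ± 0.16 and 10.83 ± 0.05 in Tconv and at 12.15 ± 0.08 and 12.01 ± 0.13 in Treg. Cd80 lay below the floor of 7 on the log2 scale in Tconv, at 6.36 ± 0.17 early and 6.49 ± 0.12 late, and at 9.10 ± 0.40 and 9.20 ± 0.11 in Treg. Ctla4 was at 9.50 ± 0.17 early and 8.62 ± 0.41 late in Tconv and at 12.33 ± 0.07 and 11.95 ± 0.12 in Treg. Pdcd1 was at 8.76 ± 0.08 and 9.23 ± 0.21 in Tconv and at 10.68 ± 0.20 and 9.86 ± 0.17 in Treg. Btla was at 9.52 ± 0.22 and 9.49 ± 0.12 in Tconv and at 9.52 ± 0.02 and 9.23 ± 0.15 in Treg. Transcript levels do not give the amount of protein on the cell surface, which was not analysed here.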
